A study of Sus scrofa with 16 samples.

How the data were processed

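Gene counts of 16 polyA RNA libraries of aortic valve interstitial cells from pigs of 5 to 6 months were used. Cells of 4 male and 4 female biological replicates had been kept for 48 hours in medium with 1% serum on hydrogels of about 5.8 kPa or on tissue culture plastic. Groups were taken from the sample labels: male gel, male plastic, female gel and female plastic, n = 4 each.

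RNA was isolated with the RNeasy Micro kit and libraries were made with the KAPA mRNA HyperPrep kit, per the labels. The deposited table holds raw counts per gene, whole numbers that fit reads assigned to annotated genes. Per the submitters' processing notes, reads were inspected with FastQC 0.11.5, trimmed with Trimmomatic 0.36, aligned with HISAT2 2.1.0 to Sscrofa11.1, handled with SAMtools 1.3.1 and counted with featureCounts, whose version and strand setting they do not give. Sense and antisense reads at overlapping genes can therefore not be told apart here, nor can reads shared between paralogs. Of 29576 entries in the table, 24 carried numbers in place of gene names and 0.169% of the counts, and were left out. The other 29552 matched RefSeq symbols, from which chromosomes and coordinates on the same build were taken. Sequence reads were not analysed here.

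Total counts ran from 16.93 to 27.48 M (mega-counts) per library. No library was a copy of another of its group: the chi-square per degree of freedom over the 24 pairs within groups was 10.46 to 87.78. Of 22139 genes with a count, 14530 passed filterByExpr by group and were tested (517 X-linked, 13699 autosomal, 31 Y-annotated, 283 without a chromosome). TMM factors ran from 0.896 to 1.124 and the median biological coefficient of variation was 0.182.

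The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on 4 group means over all 16 libraries (12 residual degrees of freedom), with Benjamini-Hochberg adjusted p under 0.05 over all tested genes as the call. Changes are log2 with their standard errors (SE), and mean counts per M (CPM) are scaled by TMM. Comparisons were plastic against gel in each sex, female against male on each surface, and the difference of the surface changes of the sexes. Tests, gene lists, alternatives and the rule for named genes were set before the data were examined.

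The naming rule took, per comparison, the 6 genes with the largest rise and the 6 with the largest fall among called genes with a symbol, a mean of at least 5 CPM in the higher group and no overlap between groups. It added up to 3 members per direction, by adjusted p, of each list with called members. Named whatever their result were EIF1AY, KDM6A, DDX3X, EIF2S3, KDM5C, EIF1AX, BMX, STS, ACTA2, TAGLN, CNN1, CTGF (the symbol of CCN2 in the table) and COL1A1. For the difference of changes it took the 3 genes with the smallest p per direction, as none passed, and for sex differences on both surfaces the 10 per direction. The text describes a part of the genes the rule gives, picked after their values were seen. Over the full rule 37 of 247 called results lost their call without some single library, against 8 of 151 in the part described. Some genes that the rule or the lists gave are not reported here. Outside the rule, TXLNG, ZFX, USP9X, GCNT1, ZNF518A and LOC396706 on gel or by another tool, GPR143, CD68, CDH5 and other endothelial markers given with their levels, LOC110255814, LOC110258600 and LOC110258214 were picked after their values were seen. XIST, and members of the Y-linked list other than EIF1AY, are not reported here, as the table gave no tested gene of that symbol.

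Of 25 gene lists, 23 had at least 5 tested members and were tested with camera of limma 3.58.1 at a correlation of 0.01, again with an estimated correlation and with fry, adjusted over lists within a comparison. The Y-linked list had 1 tested member of 18, and the epithelial and erythroid list had 0 tested members, with 15 in the table. The cardiac and skeletal muscle list had 8 tested members of 18, and the leukocyte list 5 of 23. Lists "adjusted over the list alone" took the Benjamini-Hochberg step over their members only. Chromosome shares were tested with Fisher's exact test, two-sided, and the median of X-linked minus autosomal genes with an exact permutation test over 70 assignments, two-sided. Principal components used log2 CPM with a prior count of 2 of the 500 most variable genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

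Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, CPM of at least 1 in at least 4 libraries, glmTreat against a fold of 1.2, a fit of only the 8 libraries compared, the replicate as a block, and leaving out each library. The labels do not say that a number marks the same animal on both surfaces. Deviations from group means correlated by 0.13 to 0.49 between libraries of the same sex and number. Among libraries of the same sex on the other surface, 16 of 16 libraries correlated best with their own number. Numbers within a sex were therefore read as pairs from the data and are called animals below. The main fit ignores this pairing. Its 12 residual degrees of freedom count both libraries of an animal as independent, which bears on the SE, p and intervals of all comparisons, those between the sexes included. A shared batch cannot be told apart from a shared animal. Between the sexes the same numbers gave -0.20 to 0.57, and there the block is no pairing. The 0.57, of male gel 4 and female gel 4, lay above every pair within a sex. Leaving out male gel 2 and female plastic 4, 4 further gene lists, and the list tests with an estimated correlation in the blocked fit and without the 2 libraries were chosen after the data were seen.

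The fits were tested on simulated data, with known changes put into 50 genes at each size. These were drawn from genes with a mean of at least 1 CPM, so the shares do not cover genes below that. Libraries were simulated as independent, without shared animals. In the male surface comparison 18% of 1.5-fold, 66% of 2-fold, 94% of 3-fold and 96% of 4-fold changes were called, with 7.4% wrong calls. In the sex comparison on gel the shares were 28%, 72%, 88% and 98%, with 5.3% wrong calls. Under each scaling the median log2 change over all genes stayed within 0.1 of 0. Scaling to the bulk of genes largely brings this about, so it is no check of the fits.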

Results

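The data are 16 polyA RNA libraries of porcine aortic valve interstitial cells, the fibroblast-like cells of the leaflet, from 4 male and 4 female biological replicates kept for 48 hours on a hydrogel of about 5.8 kPa or on tissue culture plastic. Each of the 4 groups (male gel, male plastic, female gel, female plastic) had n = 4. Total counts ran from 16.93 to 27.48 M (mega-counts) per library, with group means ± SD of 22.07 ± 4.28 M in male gel, 24.57 ± 1.3 M in male plastic, 25.22 ± 1.57 M in female gel and 24.49 ± 1.4 M in female plastic. Male gel 2 had the lowest total, 16.93 M, and 15476 genes with at least 1 read. After removal of Y-linked loci, the first principal component held 62.6% of the variance and parted gel from plastic in all 16 libraries. The second held 16.4% and set male 4, female 1 and female 4 apart from the other animals on both surfaces. The endothelial junction gene CDH5 (VE-cadherin), picked after its values were seen, was highest in those animals too, with 174 CPM in female plastic 1, 88.8 in female plastic 4 and 87.9 in male plastic 4, against 21.0 to 42.3 in the other plastic libraries.

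**Figure D1:**
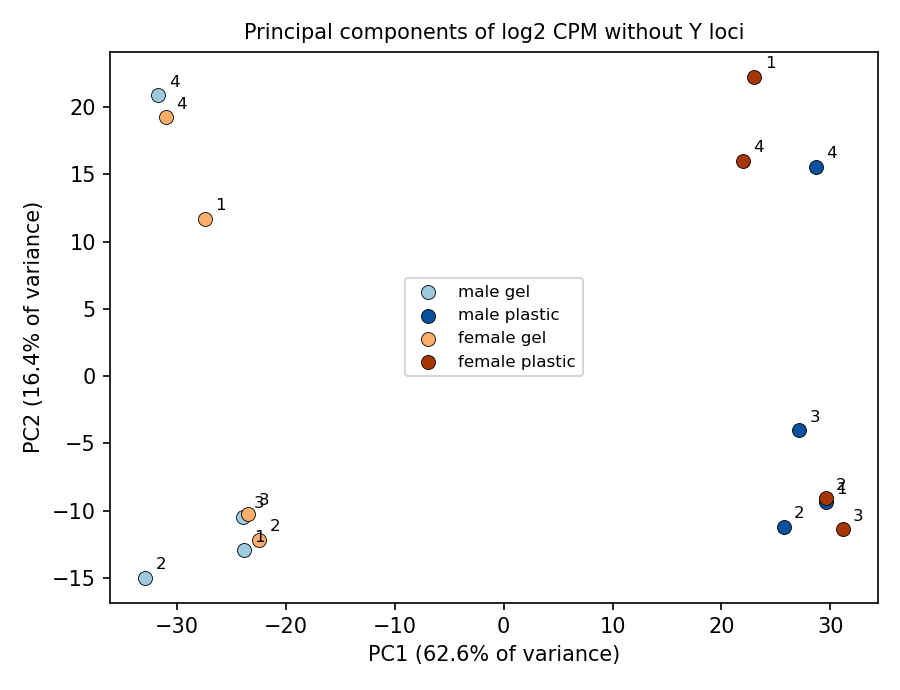
First and second principal components of log2 counts per M (CPM) over the 500 most variable genes without Y-linked loci, 16 libraries. Each point is 1 library, coloured by group, and its number is the replicate.

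The first question was how male cells on plastic, which the labels describe as myofibroblasts, differed from male cells on gel, described as quiescent fibroblasts. The 12 genes of this paragraph had the largest rises and falls among the called genes that the naming rule admits. That rule asks for a symbol and a mean of at least 5 CPM in the higher group. It also requires that all 4 plastic libraries lie on one side of all 4 gel libraries, so this separation is no finding. DES (desmin, the intermediate filament of muscle; chromosome 15, 121428539 to 121435426) rose from a mean of 0.231 to 103 CPM, a log2 change of 8.61 (SE 0.67, adjusted p = 2.43e-07). ACTA1 (skeletal muscle actin; chromosome 14, 60412651 to 60415687) rose by 7.77 (SE 0.82, adjusted p = 5.32e-06), ALKAL1 (a ligand of the receptor kinase ALK) by 6.93 (SE 0.70, adjusted p = 3.49e-06) and ACTG2 (enteric smooth muscle actin; chromosome 3, 69097366 to 69121542) by 5.60 (SE 0.48, adjusted p = 6.7e-07), from 12 ± 4.91 to 587 ± 70.3 CPM (mean ± SD, n = 4). CASQ2 (calsequestrin, a calcium store protein of muscle) rose by 4.48 (SE 0.62) and the X-linked FRMPD3 by 4.44 (SE 0.51). The deepest fall was that of AMCF-II, a porcine neutrophil-attracting chemokine (chromosome 8, 70008225 to 70010360), from 434 to 2.97 CPM, a log2 change of -7.20 (SE 0.39, adjusted p = 6.03e-09). Complement component C3 changed by -6.32 (SE 0.50, adjusted p = 3.1e-07), the acute-phase proteins SAA2 and SAA3 by -6.08 (SE 1.07) and -6.00 (SE 0.46), the protease inhibitor PI15 by -5.58 (SE 1.12) and the chemokine CXCL8 by -4.99 (SE 0.56, adjusted p = 9.4e-06). Actins and the SAA genes are families of close paralogs, and reads that fit more than 1 member cannot be told apart in a gene count table.

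In male cells the contractile and stress fibre list rose as a whole: 25 of its 25 measured genes rose, 25 adjusted over the list alone (camera adjusted p = 2e-25; adjusted p = 0.0619 with an estimated correlation, and 0.0224 with that and the replicate as a block). ACTA2 (smooth muscle alpha-actin, the standard myofibroblast marker; chromosome 14, 100868145 to 100886732) rose from 3992 ± 1071 to 19950 ± 1767 CPM, a log2 change of 2.32 (SE 0.31, adjusted p = 4.64e-05). CNN1 (calponin, an actin-binding protein of smooth muscle) rose by 2.15 (SE 0.29), VCL (vinculin, of focal adhesions) by 1.80 (SE 0.17), TAGLN (transgelin) by 1.41 (SE 0.26) and MYH9 (non-muscle myosin) by 1.31 (SE 0.13). Among markers of other cell types, 6 of the 8 tested cardiac and skeletal muscle genes (18 in the list) also rose and 0 fell. Adjusted over the list alone 6 rose (camera adjusted p = 6.26e-06, adjusted p = 0.00456 with an estimated correlation). DES, CASQ2 and TTN (titin, 2.62, SE 0.29, 20.7 to 127 CPM) were among them. DES and CASQ2 were near 0 CPM on gel and passed the filter through plastic. The filter thus partly fixed their direction and the list test. Of 11 pericyte and smooth muscle genes, 5 rose and 3 fell, and the same numbers held adjusted over the list alone (camera adjusted p = 0.000858; 0.0619 as the adjusted p with an estimated correlation). The adhesion molecule MCAM rose by 1.5 (SE 0.13) and the proteoglycan CSPG4 by 1.51 (SE 0.18), while ABCC9, a subunit of vascular potassium channels, changed by -1.87 (SE 0.41) with overlap between the groups. DES, CASQ2 and PLN are in both of these marker lists.

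Of 24 fibrillar collagen and matrix genes in male cells, 14 rose, 5 fell and 5 were not called (16 and 5 adjusted over the list alone; camera adjusted p = 0.000858; adjusted p = 0.227 with an estimated correlation). ELN (elastin) rose from 46.4 to 404 CPM, a log2 change of 3.12 (SE 0.46, adjusted p = 0.000118), and the collagens COL5A1 and COL12A1 rose by 1.13 (SE 0.15) and 0.92 (SE 0.13). COL1A1, a chain of type I collagen, rose by 0.45 (SE 0.16, adjusted p = 0.0482) from 11800 to 16160 CPM, with overlap between the groups. That call was lost without male gel 2, 3 or 4 or without any 1 of the 4 male plastic libraries, at adjusted p from 0.0568 (without male plastic 4) to 0.134 (without male gel 2). POSTN (periostin, a matricellular protein) fell (-2.36, SE 0.63, adjusted p = 0.0112), as did the collagen-crosslinking enzyme LOXL2 (-0.72, SE 0.16). Of 21 YAP/TAZ target genes, which respond to cell tension, 13 rose and 8 were not called (16 rose adjusted over the list alone, and 15 rose and 1 fell with the replicate as a block; camera adjusted p = 1.11e-07; adjusted p = 0.0449 with an estimated correlation). That call with an estimated correlation was lost without male gel 2 and female plastic 4 (adjusted p = 0.101). The genes that rose included CTGF, also named CCN2, with a log2 change of 1.63 (SE 0.32), the growth factor TGFB2 with 1.75 (SE 0.19) and CRIM1 with 1.36 (SE 0.18). The TGF-beta response list had 8 of 23 genes up and 2 down (9 and 2 adjusted over the list alone; camera adjusted p = 0.0414; adjusted p = 0.399 with an estimated correlation; 0.245 by camera without male gel 2 and female plastic 4). The growth factor TGFB3 rose by 2.6 (SE 0.25), whereas ID1 and ID2, inhibitors of differentiation factors that BMP signals induce, changed by -2.84 (SE 0.26) and -1.38 (SE 0.16).

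**Figure D2:**
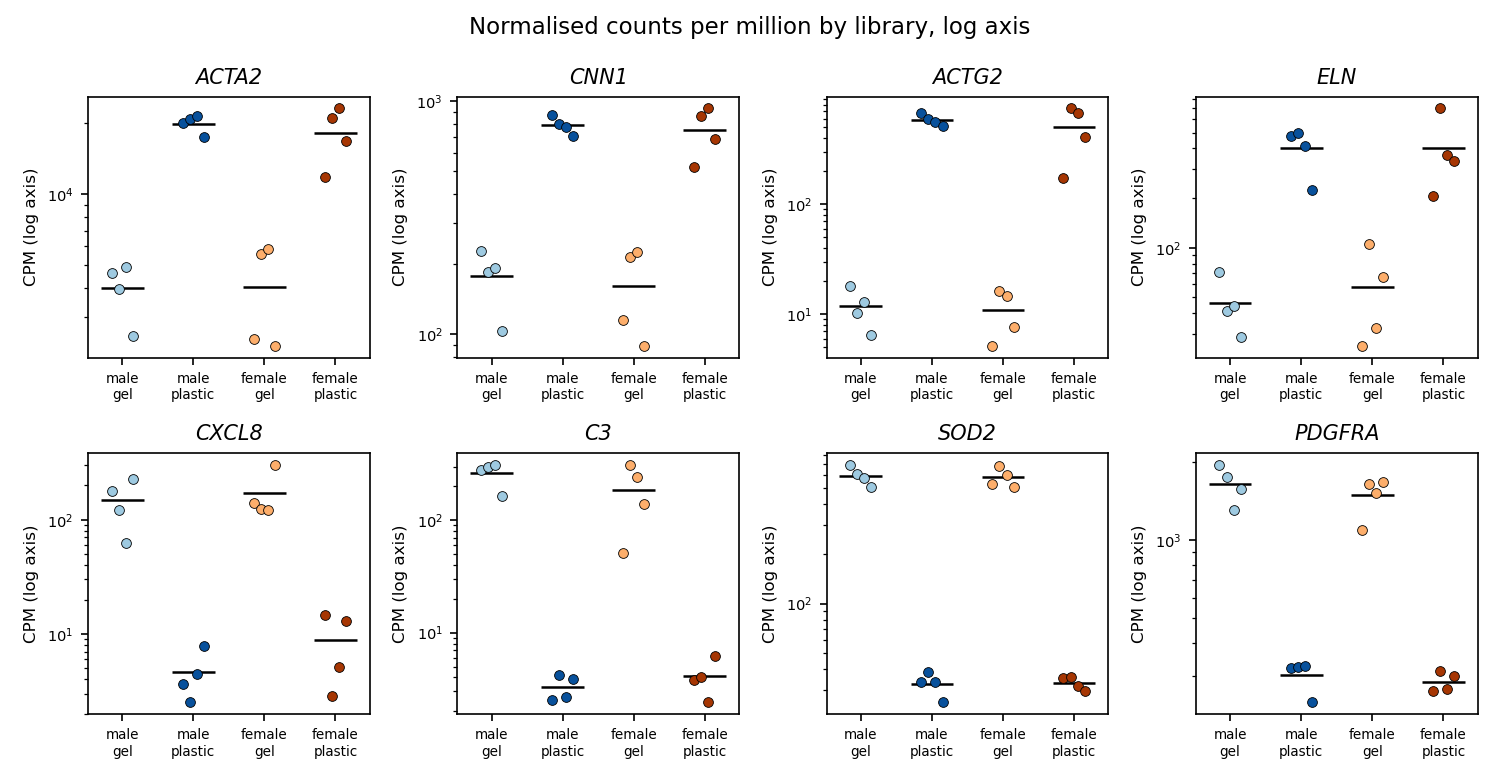
CPM of 8 genes in each library on a log axis. Points are libraries (n = 4 per group) and the line is the group mean.

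The quiescent fibroblast list moved both ways in male cells, with 7 of 23 genes up and 12 down (8 and 14 adjusted over the list alone; camera adjusted p = 0.0105, toward lower; adjusted p = 0.173 with an estimated correlation). PDGFRA, a growth factor receptor of resting fibroblasts, fell from 1649 to 303 CPM (-2.44, SE 0.16, adjusted p = 3.07e-08), and CFD, the complement activator adipsin, also fell (-3.83, SE 0.29). FMOD and PRELP, small proteoglycans that bind collagen, rose by 1.18 (SE 0.14) and 1.23 (SE 0.17). Of 23 cytokine and NF-kB target genes, 21 fell and 0 rose (21 adjusted over the list alone; camera adjusted p = 3.48e-37; adjusted p = 0.000665 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase that NF-kB induces, fell from 599 to 32.5 CPM (-4.20, SE 0.15, adjusted p = 5.05e-11), and the chemokine CXCL2 (-4.56, SE 0.21) and the adhesion molecule VCAM1 (-3.80, SE 0.22) fell with it. Interferon-stimulated genes fell too: 16 of 24, with 0 up (17 adjusted over the list alone; camera adjusted p = 1.11e-07; adjusted p = 0.0696 with an estimated correlation). IFIT1, an interferon-induced RNA-binding protein, changed by -2.91 (SE 0.44).

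Hypoxia and glycolysis genes in male cells had 2 of 24 up and 6 down (2 and 8 adjusted over the list alone; camera adjusted p = 0.0125, toward lower; adjusted p = 0.644 with an estimated correlation). The lipase inhibitor ANGPTL4 changed by -1.93 (SE 0.26), the oxygen-sensing hydroxylase EGLN3 by -1.72 (SE 0.21) and the pyruvate dehydrogenase kinase PDK1 by 0.80 (SE 0.11). For the osteogenic list (5 of 18 up, 3 down; the same adjusted over the list alone), camera gave an adjusted p = 0.854, with a median of -0.10, a mean of 0.16 and a test direction toward higher. MGP, an inhibitor of calcification, rose by 2.29 (SE 0.39) and BMP4 by 1.14 (SE 0.18), while SOX9, a cartilage transcription factor, changed by -1.56 (SE 0.16). Matrix metalloproteinases and inhibitors had 4 of 19 up and 5 down (4 and 6 adjusted over the list alone, 4 and 8 with the replicate as a block; camera adjusted p = 0.174), with MMP2 at -0.86 (SE 0.16) and MMP19 at -1.14 (SE 0.14). Cholesterol synthesis had 4 of 23 up and 0 down, among them the sterol carrier STARD4 at 1.41 (SE 0.23), and 4 adjusted over the list alone (camera adjusted p = 0.227). The unfolded protein and amino acid stress list had 2 of 23 up and 6 down, before and after adjustment over the list alone (camera adjusted p = 0.899), with VLDLR at 1.36 (SE 0.13) and DDIT4 at -1.44 (SE 0.16). The p53 and senescence list had 2 of 19 up and 4 down (2 and 6 adjusted over the list alone; camera adjusted p = 0.288), with IGFBP7 at 1.26 (SE 0.12) and SESN1 at -1.48 (SE 0.17). Immediate early genes had 9 of 24 up and 4 down (9 and 5 adjusted over the list alone, 9 and 8 with the block; camera adjusted p = 0.598, tested toward higher with a median of -0.05 and a mean of -0.09), such as the phosphatase DUSP1 at 1.15 (SE 0.14) and NR4A2 at -2.77 (SE 0.37).

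Male cell cycle genes had 3 of 30 up and 0 down, with 0 adjusted over the list alone (camera adjusted p = 0.121; adjusted p = 0.894 with an estimated correlation). With the replicate as a block they had 11 up and 2 down (camera adjusted p = 0.0393; adjusted p = 0.795 with an estimated correlation). Oxidative phosphorylation had 1 of 22 up and 2 down (1 and 0 adjusted over the list alone, 2 and 2 with the block; camera adjusted p = 0.956). X-inactivation escape genes had 5 of 31 up and 4 down, the same adjusted over the list alone (camera adjusted p = 0.942), including the kinase CDK16 at 0.43 (SE 0.07), ANOS1 (the extracellular protein anosmin) at 2.80 (SE 0.56), GPM6B at -1.49 (SE 0.20) and the steroid sulfatase STS at 0.65 (SE 0.17). The zinc finger factor ZFX changed by -0.41 (SE 0.10, adjusted p = 0.00461). EIF2S3, a subunit of translation initiation factor 2, changed by -0.40 (SE 0.13, adjusted p = 0.0339), with overlap between the groups. The EIF2S3 call was lost without male gel 2 (-0.27, adjusted p = 0.105), male gel 3 (0.0598), male plastic 1 (0.0724), male plastic 2 (0.0731) or male plastic 4 (0.0859). Not called were KDM6A (-0.02), DDX3X (-0.29, adjusted p = 0.082; 0.0299 with the replicate as a block; 0.0382 without male gel 1), KDM5C (0.29, adjusted p = 0.0768; 0.0449 by DESeq2; 0.18 and 0.0479 without male gel 2 and female plastic 4; 0.18 and 0.174 without male gel 2), EIF1AX (-0.35, adjusted p = 0.105; -0.17 and 0.36 without male gel 2), EIF1AY (-0.69, adjusted p = 0.144) and BMX (1.65, SE 0.80, adjusted p = 0.141; 0.0416 with the block). Pseudoautosomal genes had 3 of 16 up and 0 down, the same adjusted over the list alone and 3 and 1 with the block (camera adjusted p = 0.288). Sex steroid genes had 3 of 12 up and 2 down (3 and 3 adjusted over the list alone, 3 and 5 with the block; camera adjusted p = 0.551), with the steroid-reducing enzyme AKR1C1 at -3.75 (SE 0.62). Endothelial markers had 3 of 20 up and 0 down (1 adjusted over the list alone; camera adjusted p = 0.121; adjusted p = 0.8 with an estimated correlation). With the block 8 were up and 0 down (camera adjusted p = 0.0388; adjusted p = 0.543 with an estimated correlation). They included LYVE1, at 5.21 (SE 0.99) but from 0.0224 to 0.976 CPM, and ROBO4, at 3.48 (SE 1.14, adjusted p = 0.0342). The ROBO4 call was lost without any 1 of the 4 male gel libraries or without male plastic 3 or 4, at adjusted p from 0.0576 (without male plastic 4) to 0.125 (without male plastic 3). Leukocyte markers had 1 of 5 up (LAPTM5, 2.35, SE 0.65) and 1 down (CD14, the lipopolysaccharide co-receptor, -1.21, SE 0.20), the same adjusted over the list alone (camera adjusted p = 0.956).

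Over all 14530 tested genes, 3748 differed between plastic and gel in male cells, 1876 higher and 1872 lower on plastic. The change was at least 2-fold in 715 of the higher and 583 of the lower genes and at least 8-fold in 132 genes. CPM did not overlap between the groups for 4196 genes, 28.9%, where chance gives 2.86%. DESeq2 called 4216, limma-voom 3558 and the fit with the replicate as a block 4319. Without male gel 2 and female plastic 4, a choice made after the data were seen, the count was 4198 (2146 higher, 2052 lower).

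The second question was the same contrast in female cells. Desmin again led the rises, with DES at a log2 change of 8.21 (SE 0.65, adjusted p = 2.66e-07; 0.298 to 90.3 CPM). ACTA1 rose by 6.98 (SE 0.78), ALKAL1 by 6.77 (SE 0.67), ACTG2 by 5.51 (SE 0.48, adjusted p = 8.37e-07; 11 to 500 CPM), GDF7, a factor of the BMP family, by 4.76 (SE 0.76) and the membrane-bending protein PACSIN1 by 4.61 (SE 0.50). AMCF-II changed by -6.92 (SE 0.39, adjusted p = 6.34e-09), SAA3 by -6.26 (SE 0.47), SAA2 by -6.15 (SE 1.32), C3 by -5.49 (SE 0.48) and the extracellular glutathione peroxidase GPX3 by -5.34 (SE 0.44). The naming rule requires that all 4 female plastic libraries lie on one side of all 4 female gel libraries, so this holds for each of these 11 genes by selection.

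Of the 25 contractile and stress fibre genes, 23 rose in female cells, 0 fell and 2 were not called (23 adjusted over the list alone; camera adjusted p = 2.53e-24; adjusted p = 0.079 with an estimated correlation, and 0.0244 with that and the replicate as a block). ACTA2 rose from 4024 to 18200 CPM (2.18, SE 0.31, adjusted p = 8.85e-05), CNN1 by 2.23 (SE 0.29), VCL by 1.84 (SE 0.17) and TAGLN by 1.21 (SE 0.25, adjusted p = 0.00225). Beside it, 5 of 8 tested cardiac and skeletal muscle markers rose, among them TTN (2.34, SE 0.29) and CASQ2 (3.76, SE 0.58). Adjusted over the list alone 6 rose (camera adjusted p = 6.44e-05, adjusted p = 0.00829 with an estimated correlation). The limit set by the filter in male cells holds here too. Of 11 pericyte and smooth muscle markers, 5 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.00492; adjusted p = 0.124 with an estimated correlation), with CSPG4 at 1.17 (SE 0.17) and ABCC9 at -1.88 (SE 0.41). The collagen and matrix list had 13 of 24 up, 4 down and 7 not called (14 and 4 adjusted over the list alone; camera adjusted p = 6.44e-05; adjusted p = 0.137 with an estimated correlation). COL12A1 rose by 1.15 (SE 0.14), COL5A1 by 1.06 (SE 0.15) and COL5A2 by 0.71 (SE 0.10). COL1A1 was not called (0.37, SE 0.16, adjusted p = 0.113), though it was without female gel 2 (0.50, adjusted p = 0.0375). POSTN fell (-2.27, SE 0.63, adjusted p = 0.0144), with overlap between the groups and not without female gel 1 (-1.34, adjusted p = 0.0853). LOXL2 also fell with overlap (-0.53, SE 0.16, adjusted p = 0.0203). Its call was lost without female gel 2 (adjusted p = 0.0652), female gel 4 (0.0501), female plastic 2 (0.0524), female plastic 3 (0.0683) or female plastic 4 (0.0519).

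YAP/TAZ targets in female cells had 11 of 21 up, 1 down and 9 not called (15 and 1 adjusted over the list alone; camera adjusted p = 7.92e-07; adjusted p = 0.0645 with an estimated correlation, and 0.0244 with that and the replicate as a block), with CTGF at 1.58 (SE 0.32), TGFB2 at 2.04 (SE 0.19) and CRIM1 at 1.34 (SE 0.18). The TGF-beta response list had 10 of 23 up and 5 down (10 and 6 adjusted over the list alone; camera adjusted p = 0.227; adjusted p = 0.678 with an estimated correlation). With the replicate as a block the camera adjusted p was 0.0408 (adjusted p = 0.46 with an estimated correlation). TGFB3 rose by 2.40 (SE 0.24), while ID1 changed by -3.86 (SE 0.27), ID2 by -1.56 (SE 0.16) and the inhibitory SMAD6 by -0.91 (SE 0.19). Quiescent fibroblast genes had 4 of 23 up and 11 down (7 and 12 adjusted over the list alone, and the same with the block; camera adjusted p = 0.00171; adjusted p = 0.102 with an estimated correlation). PDGFRA changed by -2.38 (SE 0.16, adjusted p = 4.58e-08) and CFD by -4.16 (SE 0.30), against FMOD at 1.07 (SE 0.14) and PRELP at 1.13 (SE 0.17). Cytokine and NF-kB targets fell, 20 of 23 with 0 up (21 adjusted over the list alone; camera adjusted p = 1.45e-36; adjusted p = 0.000564 with an estimated correlation): SOD2 (-4.15, SE 0.15, adjusted p = 5.99e-11), CXCL2 (-4.36, SE 0.21) and the NF-kB inhibitor NFKBIA (-2.6, SE 0.16). Of 24 interferon-stimulated genes 10 fell and 0 rose (10 adjusted over the list alone; camera adjusted p = 0.000196; adjusted p = 0.22 with an estimated correlation), including IFI44L at -1.02 (SE 0.16) and IFIT1 at -2.56 (SE 0.44).

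Matrix metalloproteinases and inhibitors in female cells had 3 of 19 up and 7 down (4 and 10 adjusted over the list alone; camera adjusted p = 0.0489; adjusted p = 0.34 with an estimated correlation; 0.0626 by camera without male gel 2 and female plastic 4). MMP19 changed by -1.25 (SE 0.14), MMP2 by -0.85 (SE 0.16) and the aggrecan-cleaving ADAMTS4 by -1.58 (SE 0.33). Hypoxia and glycolysis had 1 of 24 up and 7 down, the same adjusted over the list alone (camera adjusted p = 0.00742; adjusted p = 0.582 with an estimated correlation), with ANGPTL4 at -1.95 (SE 0.26), EGLN3 at -1.57 (SE 0.21) and PDK1 at 0.94 (SE 0.12). Osteogenic genes had 4 of 18 up and 3 down, the same adjusted over the list alone and 4 and 5 with the replicate as a block (camera adjusted p = 0.912), with BMP4 at 0.88 (SE 0.17), SOX9 at -1.33 (SE 0.16) and BMP2 at -1.85 (SE 0.41). Cholesterol synthesis had 3 of 23 up and 1 down (2 and 1 adjusted over the list alone, 5 and 1 with the block; camera adjusted p = 0.367), with STARD4 at 2.0 (SE 0.23). The unfolded protein list had 2 of 23 up and 3 down (camera adjusted p = 0.808) and the p53 list 2 of 19 up and 4 down (2 and 5 adjusted over the list alone, 2 and 7 with the block; camera adjusted p = 0.144). DDIT4 changed by -1.47 (SE 0.16), VLDLR by 1.27 (SE 0.13), IGFBP7 by 1.09 (SE 0.12) and SESN1 by -1.49 (SE 0.17). Immediate early genes had 4 of 24 up and 5 down (camera adjusted p = 0.944), among them NR4A2 at -2.72 (SE 0.36) and DUSP1 at 0.81 (SE 0.14). Both the unfolded protein and the immediate early list had the same numbers adjusted over the list alone.

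Female cell cycle genes had 1 of 30 up and 0 down (0 adjusted over the list alone, 7 up and 2 down with the replicate as a block; camera adjusted p = 0.227), and oxidative phosphorylation 1 of 22 up and 3 down (1 and 2 adjusted over the list alone; camera adjusted p = 0.227). Among X-inactivation escape genes, 8 of 31 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.118): CDK16 rose by 0.41 (SE 0.07), ANOS1 by 3.31 (SE 0.60) and STS by 0.91 (SE 0.17), and GPM6B changed by -0.89 (SE 0.20). BMX, a non-receptor tyrosine kinase, rose by 2.48 (SE 0.77, adjusted p = 0.028) from 3 to 12 reads per library on gel to 3 to 77 on plastic, with overlap. Its call was lost without female gel 1 (adjusted p = 0.0628), female gel 3 (0.0811), female gel 4 (0.0782) or female plastic 1 (1.38, adjusted p = 0.183). KDM6A (0.04), DDX3X (-0.03), EIF2S3 (-0.06), KDM5C (0.02) and EIF1AX (0.17) were not called. Pseudoautosomal genes had 2 of 16 up and 1 down (3 and 1 adjusted over the list alone; camera adjusted p = 0.772). Sex steroid genes had 2 of 12 up and 2 down, the same adjusted over the list alone and 2 and 4 with the block (camera adjusted p = 0.748), with AKR1C1 at -4.10 (SE 0.60). Endothelial markers had 4 of 20 up and 0 down, the same adjusted over the list alone (camera adjusted p = 0.0881; adjusted p = 0.754 with an estimated correlation). With the block 7 were up and 0 down (camera adjusted p = 0.0223; adjusted p = 0.46 with an estimated correlation). The endothelial transcription factor ERG rose by 0.73 (SE 0.16), ROBO4 by 6.35 (SE 1.35, with overlap) and LYVE1 by 4.04 (SE 0.96, with overlap, and 6.65 without female gel 3). ROBO4 and LYVE1 were near 0 CPM on gel, at most 0.118 and 0.102. On plastic ROBO4 stood at 10.75 CPM in female plastic 1 and at 0.084 to 1.54 in the others, and LYVE1 at 0.089 to 0.842. Leukocyte markers had 1 of 5 up and 1 down (camera adjusted p = 0.622): CD14 changed by -1.40 (SE 0.20) and LAPTM5 by 2.14 (SE 0.61, adjusted p = 0.0176), the latter with overlap and not called without female plastic 1 (1.16, adjusted p = 0.116) or female gel 3 (1.86, adjusted p = 0.0549).

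In all, 3476 genes differed between the surfaces in female cells, 1839 higher and 1637 lower on plastic. The change was at least 2-fold in 628 of the higher and 568 of the lower genes and at least 8-fold in 115. CPM did not overlap for 4022 genes, 27.7%, against 2.86% by chance. DESeq2 called 3937, limma-voom 3500 and the blocked fit 4011. Without male gel 2 and female plastic 4 the count was 4291 (2167 higher, 2124 lower).

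**Figure D3:**
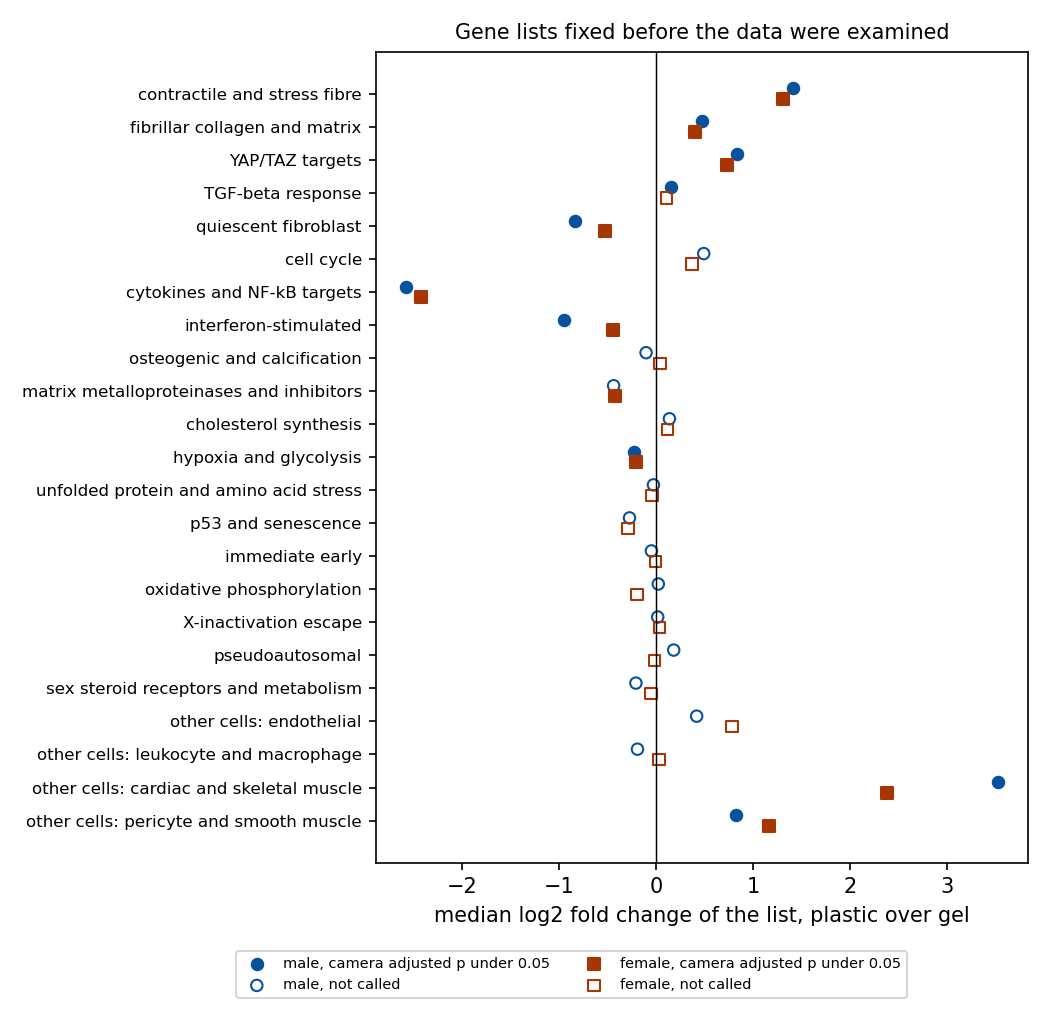
Median log2 change from gel to plastic in male and in female cells, for each fixed gene list with at least 5 tested members. Filled symbols mark lists with a camera adjusted p under 0.05 at a preset correlation of 0.01.

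How alike the sexes responded was asked next. On plastic 1342 genes rose and 1056 fell in both sexes, where independent calls would give 237.4 and 210.9, and 0 genes were called in opposite directions. Of the 4826 genes called in either sex, 97.6% had the same sign in both. Across genes, which are not independent replicates, the log2 changes of the sexes had a Pearson correlation of 0.845 and a Spearman correlation of 0.698, and a Pearson correlation of 0.884 over the 10205 genes with a mean of at least 5 CPM. Without male gel 2 and female plastic 4 the shared count was 3332, against 2398 with all libraries.

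**Figure D4:**
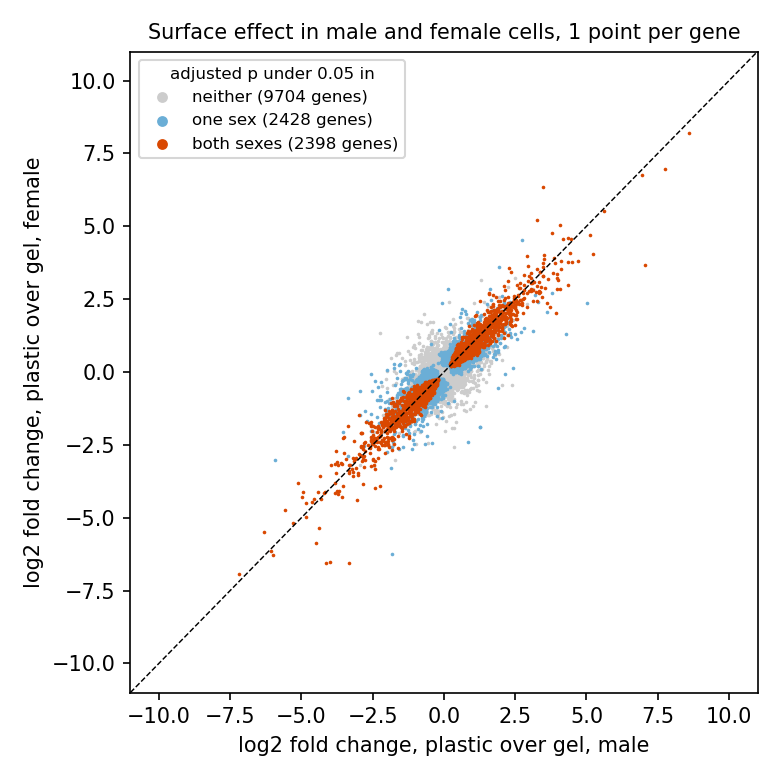
Log2 change from gel to plastic of each tested gene in male (x) and female (y) cells. The dashed line marks equality, and colours mark genes called in both sexes, in one sex or in neither.

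A further question was which genes differed between female and male cells on gel. The histone demethylase KDM6A (X chromosome, 39953764 to 40154197) was higher in female cells, 44.4 ± 2.59 against 28.8 ± 2.57 CPM, a log2 difference of 0.62 (SE 0.09, adjusted p = 0.00581), with all 4 female libraries above all 4 male ones. It was the 1 gene called higher. ZFX (0.51, SE 0.10, adjusted p = 0.0562), TXLNG (0.58, SE 0.12, adjusted p = 0.102), which encodes the trafficking protein gamma-taxilin, and EIF2S3 (0.61, SE 0.13, adjusted p = 0.206) did not pass, although their groups did not overlap. DESeq2 called ZFX (adjusted p = 0.000784), TXLNG (0.00177) and EIF2S3 (0.0194). It also called 3 genes lower in female cells that edgeR did not: the autosomal GCNT1 (-0.64, adjusted p = 0.029) and ZNF518A (-0.48, adjusted p = 0.029) and the Y locus LOC396706 (-2.41, adjusted p = 0.000784). EIF2S3 was also called without male gel 2 (0.75, adjusted p = 0.0103). Differences were not called for DDX3X (0.30, adjusted p = 0.852), KDM5C (0.13, 95% interval -0.12 to 0.38), EIF1AX (0.03, -0.30 to 0.35), STS (-0.31, -0.67 to 0.05) or BMX (-0.01, -1.65 to 1.63). Myofibroblast genes were not called either: ACTA2 differed by 0.01 (-0.62 to 0.64), TAGLN by 0.01 (-0.52 to 0.54), CNN1 by -0.14 (-0.73 to 0.44), CTGF by -0.17 (-0.83 to 0.49) and COL1A1 by -0.07 (-0.41 to 0.27).

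On gel 15 genes differed between the sexes, 1 higher and 14 lower in female cells, with 560 at an unadjusted p under 0.05. CPM did not overlap between the sexes for 295 genes, 2%, against 2.86% by chance. DESeq2 called 21, limma-voom 16 and the fit without male gel 2 and female plastic 4 17 (3 higher, 14 lower). Interferon-stimulated genes leaned lower in female cells with 0 of 24 called, over all genes and adjusted over the list alone (camera adjusted p = 0.00686; adjusted p = 0.786 with an estimated correlation). X-inactivation escape genes had 1 of 31 called (4 adjusted over the list alone; camera adjusted p = 0.162; adjusted p = 0.786 with an estimated correlation). Without male gel 2 and female plastic 4, a choice made after the data were seen, 3 of this list were called (camera adjusted p = 0.000138; adjusted p = 0.0437 with an estimated correlation). Apart from EIF1AY of the Y-linked list, the other lists had 0 members called.

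On plastic, 4 X-linked genes were higher in female cells, each with all 4 female libraries above all 4 male ones. ZFX (X chromosome, 20220812 to 20273689) stood at 75.2 against 43.5 CPM, a log2 difference of 0.79 (SE 0.10, adjusted p = 0.000355), KDM6A at 45.5 against 28.5 CPM (0.68, SE 0.09, adjusted p = 0.00189) and EIF2S3 (20129708 to 20162881) at 164 against 84.9 CPM (0.95, SE 0.13, adjusted p = 0.00189). TXLNG (13229680 to 13292371) was higher by 0.70 (SE 0.12, adjusted p = 0.0131), 22.8 against 14 CPM. The TXLNG call was lost without male plastic 1 (0.62, adjusted p = 0.0655), male plastic 2 (0.69, 0.0748) or female plastic 4 (0.62, 0.0598). Not called were the RNA helicase DDX3X (0.57, adjusted p = 0.138; 0.00395 by DESeq2), the deubiquitinase USP9X (0.45, adjusted p = 0.0955; 0.000716 by DESeq2) and EIF1AX (0.55, 95% interval 0.22 to 0.88, adjusted p = 0.98), whose groups did not overlap. KDM5C differed by -0.14 (-0.39 to 0.10), STS by -0.05 (-0.40 to 0.31) and BMX by 0.82 (-0.68 to 2.32). ACTA2 differed by -0.13 (-0.76 to 0.50), TAGLN by -0.19 (-0.72 to 0.34), CNN1 by -0.07 (-0.65 to 0.52), CTGF by -0.21 (-0.88 to 0.45) and COL1A1 by -0.15 (-0.49 to 0.19), none of them called.

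**Figure D5:**
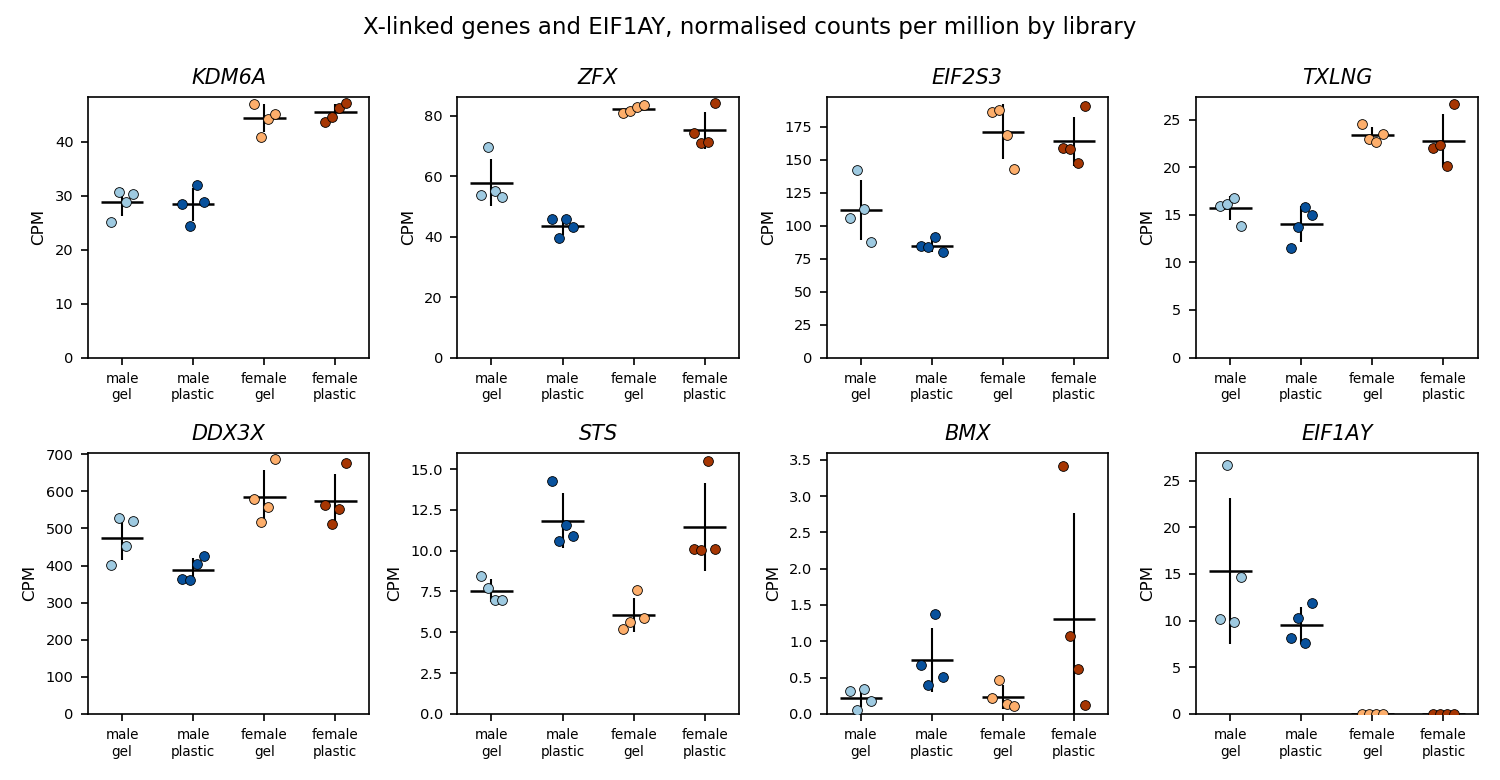
CPM of 8 genes annotated to the X or Y chromosome in each library on a linear axis. Whether STS, at 3926027 to 4076900 on X, lies in the part shared with Y was not tested. Points are libraries (n = 4 per group), the line is the group mean and the bar is the SD.

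Between the sexes 18 genes differed on plastic, 4 higher and 14 lower in female cells, with 284 at an unadjusted p under 0.05. Groups did not overlap for 414 genes, 2.8%, where chance gives 2.86%. DESeq2 called 20, limma-voom 18 and the fit without male gel 2 and female plastic 4 20 (6 higher, 14 lower). The X-inactivation escape list was higher in female cells (4 of 31 called, 8 adjusted over the list alone; camera adjusted p = 2.07e-10; adjusted p = 0.00284 with an estimated correlation). Contractile genes had 0 called and a camera adjusted p = 0.0594 toward lower in female cells (adjusted p = 0.918 with an estimated correlation). ACTA2 of this list stood at 11870 CPM in female plastic 1 and 16780 in female plastic 4, which the second component set apart. In female plastic 2 and 3 it stood at 21000 and 23140 CPM. Male plastic 4, which that component also set apart, stood at 17470 CPM, against 19970 to 21480 in the other male plastic libraries. Without male gel 2 and female plastic 4 the camera adjusted p of the list was 0.181, still toward lower. Leaving out female plastic 1 or male plastic 4 was not tested for this list. Pseudoautosomal genes (camera adjusted p = 0.052) and endothelial markers (0.0712, toward higher in female cells) also had 0 called, as did all other lists but the Y-linked one. Adjusted over the list alone, 1 pseudoautosomal gene was lower in female cells, GPR143 (-0.93, adjusted p = 0.875 over all genes), a pigment cell receptor. KDM6A was the 1 gene higher in female cells on both surfaces, and 14 genes were lower on both.

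Each gene called higher in female cells, on either surface, was X-linked. The share of X-linked genes (517 tested) against autosomal genes (13699 tested) among these calls gave p = 0.0364 on gel (1 X-linked, 0 autosomal) and p = 1.73e-06 on plastic (4 X-linked, 0 autosomal) by Fisher's exact test, two-sided. With 1 call, the gel value is only the X-linked share of these tested genes. The 4 calls on plastic are all in the escape list, and without the escape and pseudoautosomal lists no call was left. Without male gel 2 the gel value was 4.73e-05. Among genes lower in female cells, 0 X-linked and 1 autosomal were called by edgeR on each surface (p = 1, Fisher's exact test, two-sided). The autosomal call was the pseudogene LOC110260815, which had at most 1 read in any female library and is described with the Y loci below. The shift of X-linked genes as a class did not pass the test on either surface with the main filter: the median log2 CPM of X-linked minus autosomal genes was -0.43 ± 0.03 in female and -0.40 ± 0.11 in male cells on gel, a difference of -0.03 (exact permutation p = 0.8, two-sided, 70 assignments). On plastic it was -0.28 ± 0.02 and -0.33 ± 0.07, a difference of 0.05 (exact permutation p = 0.2, two-sided, smallest possible 0.0286). Over genes with a CPM of at least 1 in at least 4 libraries the difference on plastic was 0.063 and passed (exact permutation p = 0.0286, two-sided), and on gel it was -0.047 (exact permutation p = 0.4).

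Of 31 tested loci annotated to the Y chromosome, 13 were lower in female cells on both surfaces and 18 were called on neither by edgeR, of which DESeq2 called LOC396706 lower on gel. EIF1AY, a translation initiation factor (Y chromosome, 9687350 to 9704489), had 264 to 472 reads per male library on gel and 167 to 282 on plastic, and 0 in all 8 female libraries. Against a floor of 3 counts per library, which covers counting error only, it was at least 140-fold lower in female cells on gel and at least 71-fold lower on plastic. Of the unnamed Y loci, LOC100625207 had means of 90.9 CPM in male and 0.0889 CPM in female cells on gel, and LOC100624329 44.4 against 8.68 CPM. The 14th gene lower on both surfaces, LOC110260815, is a pseudogene annotated to chromosome 5 (84719269 to 84727781), with 52 to 122 reads per male library on gel, 62 to 73 on plastic and at most 1 per female library. At the 13 Y loci called lower, each male library had more reads than any female library, which matches the sex labels. Reads at the 18 others do not mark sex in this way. Among those, picked after their values were seen, CD99 (402 CPM in male and 390 in female cells) and XG (75.5 and 76) are in the pseudoautosomal list.

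The last question was whether the change from gel to plastic differed between the sexes. By edgeR 0 genes passed, with 633 at an unadjusted p under 0.05 and a smallest adjusted p of 0.767, and DESeq2, limma-voom and the blocked fit also called 0 (772, 502 and 906 unadjusted). Without male gel 2 and female plastic 4 the count was 0 as well (214 unadjusted). The genes with the smallest p, none of which passed, were ZNF518A (0.61, SE 0.16), PTBP2 (0.54, SE 0.14) and CADPS2 (0.71, SE 0.21) upward and ATOH8 (-1.03, SE 0.33), CHCHD4 (-0.63, SE 0.21) and ID1 (-1.02, SE 0.35) downward, as female minus male change. For ACTA2 the difference of changes was -0.14 (95% interval -1.03 to 0.75), for BMX 0.83 (-1.53 to 3.19), for STS 0.26 (-0.24 to 0.77), for KDM6A 0.05 (-0.23 to 0.34) and for EIF2S3 0.34 (-0.05 to 0.73). Interferon-stimulated genes and X-inactivation escape genes leaned toward a more positive change in female cells (camera adjusted p = 0.0259 each; adjusted p = 0.956 and 0.666 with an estimated correlation), with 0 members called, over all genes and adjusted over the list alone. Of the leukocyte list 1 gene, CD68 (-2.13, adjusted p = 0.767 over all genes, group means of at most 0.436 CPM), passed when adjusted over the list alone. The median SE of a difference of changes was 0.258 log2 units. This SE and the intervals come from the fit of group means, which ignores the pairing of numbers within a sex.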

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

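The tests of endothelial markers, depth, gene span and BMX, and the splits of the libraries in the surface and sex comparisons, were chosen after the results were seen; the split test of the difference of changes was set before. A library stood far from the other 3 of its group (gap to the nearest over the range, above Dixon's 95% critical value) in 48 of 692 groups tested over 153 genes, the gene lists, total counts and the X-linked median, where chance gives about 35. Values below are that ratio on the scale of log2 CPM or, for lists, its mean.

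In male gel, library 2 was lowest for the TGF-beta response list (0.854), LATS2 (0.913), CFD (0.909) and KDM5C (0.863) and highest for ZFX (0.871) and ZNF518A (0.969). Library 4 was lowest for the quiescent fibroblast list (0.908), SESN1 (0.837) and ABCC9 (0.901) and highest for SRD5A1 (0.91) and LYVE1 (1, the others at 0 reads). CASQ2 was highest in library 3 (0.934) and MFAP5 lowest in library 1 (0.833). In male plastic, library 1 had the lowest total (0.917) and XPC (0.904) and the highest FRMPD3 (0.918) and ZNF518A (0.889). Library 4 was lowest for the contractile list (0.881), the pericyte list (0.94), MYH9 (0.914), PDGFRA (0.942), KCNJ8 (0.956) and TAGLN (0.961) and highest for TTN (0.87), and library 2 was lowest for IER3 (0.979).

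In female gel, library 4 was highest for the cytokine list (0.867), the hypoxia list (0.921) and CXCL8 (0.842) and lowest for the X-inactivation escape list (0.941), the pericyte list (0.854), TMSB4X (0.878) and KCNJ8 (0.957). Library 1 was lowest for SAA3 (0.857) and DUSP1 (0.883), library 2 highest for COL5A1 (0.935) and GPM6B (0.842), and library 3 highest for ATP5F1 (0.847) and CTSK (0.877). In female plastic, library 1 was highest for KIF20A (0.888), PRKX (0.87) and GDF7 (0.839) and lowest for CTSK (0.921). Library 3 was highest for BMP4 (0.843) and STS (0.984). Library 4 was highest for TTN (0.929) and NDUFA4L2 (0.83) and lowest for CSPG4 (0.883) and SLC25A6 (0.872). The change from gel to plastic differed between the sexes by camera for the interferon-stimulated list (adjusted p = 0.0259) and the X-inactivation escape list (0.0259), with 0 members called and adjusted p = 0.956 and 0.666 with an estimated correlation.

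Endothelial markers differed between animals. Over the 8 animals the median correlation of each of 20 markers, none of them in another list, with the mean of the others was 0.88, at percentile 100 of 1000 random lists of like expression (random median 0.04, 95th percentile 0.33). ENG (168 CPM), ERG (138), PECAM1 (56.1), CDH5 (40.3) and FLT1 (40.0) were the most abundant, and 14 markers correlated above 0.7, but ROBO4 (0.41), ERG (0.22), VWF (-0.25) and LYVE1 (-0.62) followed weakly or not at all, so that a differing share of endothelial cells may account for the pattern but stays open; the condition that VWF follow was added after a first result. Library depth stays open too. Total counts and the endothelial mean had r = 0.16 on gel (n = 8, exact permutation p = 0.704, two-sided, with rho = 0.00, p = 1, and r = -0.55 without the 2 farthest libraries). On plastic r was -0.27 (exact permutation p = 0.551, with rho = 0.12, p = 0.793, and r = 0.28 without the 2 farthest). The adjusted p was 0.772 for both r over 4 relations. With 8 libraries per surface, values of this size leave strong relations of either sign possible, so they decide nothing. The labels name no sort that would remove such cells, and differences between the animals themselves were not tested.

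Male gel 2 and female plastic 4 departed from their groups in a like way: their deviations correlated by 0.30 across genes, and 8 of 96 pairs of libraries from different groups correlated more. Their root mean square deviations were 0.639, the largest of all, and 0.426 log2 units, the latter below female plastic 1 of the same group (0.446) and male gel 4 (0.454). Low depth does not account for both, since all 3 other libraries of its group had fewer counts than female plastic 4. The genomic span of genes may play a part: deviation and span had a Spearman correlation of 0.22 in male gel 2 and 0.22 in female plastic 4 over 14512 genes, against -0.19 to 0.14 in the other 14 libraries, but over the 6494 genes with at least 20 CPM 0.27 and 0.29 stood above the highest of the others, 0.24, by a margin of 0.026, so this stays open. GC content was not tested, and no biological explanation was tested.

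BMX reads differed widely within groups, from 3 to 77 on female plastic, with 77 in female plastic 1, the library with the most CDH5 (174 CPM). Endothelial cells could carry these reads: over the 8 plastic libraries BMX and the endothelial mean had r = 0.56 (exact permutation p = 0.161, two-sided; rho = 0.26, p = 0.536), adjusted p = 0.644 over 4 relations. Without the 2 farthest libraries r was -0.12, so the relation rests on those, and on gel r was 0.12 (p = 0.772; rho = 0.17, p = 0.703; r = -0.45 without 2). The counts decide nothing between this and a difference between animals, which was not tested.

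Each comparison was set against all 35 splits of its 8 libraries, which ignore the pairing of numbers within a sex. In 4 comparisons the real split was the 1 of 35 with a count as large. For the surface these were the male count (3748, highest other split 0) and the female count (3476, highest other 1). For sex they were the count on gel (15, highest other 9) and on plastic (18, highest other 0). Of the sex calls, 13 on each surface were Y loci, which only the true sex labels separate. Every other split of a surface comparison mixes gel and plastic on both sides, which widens the spread within each side. The real split was thus bound to rank high, so its rank does not exclude chance. Only 8 splits of a surface comparison part all 4 pairs, too few for a share under 0.05, and the highest count of the 7 others was 0 in each sex. For the difference of changes, the real split and the other splits of the 8 animals all called 0; a real count of 0 makes 35 of 35 certain, so these splits decide nothing.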

How the results depend on the processing

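Leaving out male gel 2 and female plastic 4 together was chosen after the results were seen, the other settings before unless stated. In simulated data with 50 genes of at least 1 CPM changed at each size, small changes were mostly missed. Of 1.5-fold changes, 18% (male surface) and 28% (sex on gel) were called. The real surface comparisons called far more genes, 3748 and 3476, which loosens the cut-off of the adjusted p. The simulated shares therefore do not carry over to them. Counts of called genes stayed within 1.5 times under RLE factors, other filters, limma-voom, DESeq2, the block and only the 8 libraries compared, and fell to 2189 (male) and 2024 (female) with glmTreat, which by construction asks for more than a 1.2-fold change. Without each library in turn they were 2859 to 3609 (male surface), 2780 to 3260 (female surface), 15 to 17 (sex, gel), 16 to 17 (sex, plastic), 0 (difference of changes), 2055 to 2916 (surface, both sexes) and 14 to 17 (sex, both surfaces). Fixed lists called, in the order male surface, female surface, sex on gel, sex on plastic and difference of changes, were 10, 10, 1, 1 and 2. With an estimated correlation they were 3, 2, 0, 1 and 0, with directional fry 12, 12, 0, 1 and 0, with mixed fry 22, 22, 1, 1 and 0, and with the block 12, 12, 1, 2 and 2, or 4, 4, 0, 1 and 0 with an estimated correlation too, the last chosen after the results were seen. Between the sexes, where the block is no pairing, it called 14 genes on gel and 18 on plastic, DDX3X on plastic among them (adjusted p = 0.0342), and gave contractile genes on plastic a camera adjusted p = 0.0278 (adjusted p = 0.892 with an estimated correlation). Fry does not compare a list with other genes. The median of X-linked genes differed by 0.063 on plastic at a CPM of at least 1 (exact permutation p = 0.0286, the smallest possible; 0.0286 to 0.486 over its alternatives), and on gel by -0.058 (without male gel 4) to 0.02 (without male gel 2). No value came from the X-linked share without the escape and pseudoautosomal lists, as no call was left. Over all 285 results of single genes, 282 kept direction and call with RLE factors, 281 with DESeq2, 277 with the block and 273 without the pair of libraries, and 37 of 247 called results lost their call without 1 library. In none of the called results did the direction turn. The differences that reversed had not been called, and all but BMX on plastic (0.82) lay within 0.2 of 0. KDM6A in the male surface comparison was 0.02 without the pair and -0.08 to 0.05 without 1 library; in the female one DDX3X was -0.11 to 0.06 and KDM5C -0.04 to 0.10 without 1 library. Between the sexes on gel, BMX was 0.02 with DESeq2, 0.05 with the block and -0.58 to 0.24 without 1 library, ACTA2 -0.07 with the block and -0.22 to 0.21, TAGLN -0.03 with the block and -0.14 to 0.16, EIF1AX -0.06 to 0.21, CNN1 -0.35 to 0.06, CTGF -0.39 to 0.11 and COL1A1 -0.20 to 0.06. On plastic, STS was 0.01 without the pair and -0.23 to 0.05 without 1 library, BMX -0.29 to 1.31, ACTA2 -0.27 to 0.03 and CNN1 -0.19 to 0.08. For changes other than that of glmTreat the cause was not tested.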

Other observations

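The 4 lists in this part, and the loci named in it, were chosen after the values were seen, so their tests are not independent evidence. Complement genes fell on plastic in both sexes, 10 of 18 with 0 up (camera adjusted p = 1.46e-07 male and 3.3e-08 female, and adjusted p = 0.0209 and 0.0155 with an estimated correlation). The 18 include F3, a coagulation gene that is also in the YAP/TAZ list. It leaned the other way and was not called (1.64 in male and 1.55 in female cells). C7, of the membrane attack complex, changed by -4.32 (SE 0.95) in male and -4.36 (SE 0.97) in female cells, the activator CFB by -3.57 (SE 0.49) and -3.17 (SE 0.49), and the initiating proteases C1R by -2.50 (SE 0.35) and -2.32 (SE 0.35) and C1S by -2.52 (SE 0.46) and -2.46 (SE 0.46), n = 4 per group. Genes of the striated muscle Z-disc and sarcomere rose, 15 of 19 in each sex with 1 down in male and 0 in female cells (camera adjusted p = 5.05e-19 and 1.13e-17; adjusted p = 0.0057 and 0.00687 with an estimated correlation). The small heat shock protein HSPB7 rose by 3.87 (SE 0.35) and 3.90 (SE 0.35), the laminin receptor ITGA7 by 3.40 (SE 0.41) and 2.91 (SE 0.40) and the Z-disc protein LDB3 by 3.16 (SE 0.41) and 3.11 (SE 0.41). Between the sexes, 0 members of either list were called on either surface.

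The insulin-like growth factor axis moved both ways, with 4 of 14 genes up and 3 down in each sex (camera adjusted p = 0.118 male, 0.494 female). IGF1 changed by -4.63 (SE 0.45) in male and -4.45 (SE 0.44) in female cells and PAPPA, a protease that frees it from binding proteins, by -1.59 (SE 0.21) and -1.60 (SE 0.20). The binding protein IGFBP5 rose by 3.66 (SE 0.47) and 3.19 (SE 0.46) and the receptor IGF1R by 0.95 and 1.00 (SE 0.09 each). Of 14 genes in the prostanoid and angiotensin list, 2 rose and 5 fell in each sex (camera adjusted p = 0.0109 and 0.00151, toward lower, and adjusted p = 0.0209 and 0.00941 with an estimated correlation). That list also holds the endothelin receptors EDNRA and EDNRB, which were not called in either sex. The angiotensin receptor AGTR1 rose by 2.52 and 2.48 and the thromboxane receptor TBXA2R by 2.80 and 2.53, with SE from 0.32 to 0.33. Angiotensinogen, AGT, changed by -2.59 and -2.56, the cyclooxygenase PTGS1 by -2.07 and -2.40 and the prostaglandin receptor PTGFR by -2.30 and -1.97.

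LOC110255814, a pseudogene on chromosome 11, had up to 192 reads on gel and 160 on plastic in female cells, from animals 1 and 3 alone, and at most 1 read in any male library. LOC110258600, an unplaced locus, varied from 3640 to 114721 reads per library, and LOC110258214 from 2879 to 88308.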
